A study of Mus musculus with 47 samples.

How the data were processed

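Total RNA of muscle progenitor cells, sorted by flow cytometry from the back muscle of E17.5 mouse embryos, was measured on Illumina bead arrays after amplification to biotin-labelled cRNA, per the labels. The series holds 47 arrays of 5 genotypes on 7 chips. The deposited probe table gives the signal intensity of each probe on each array on a linear scale, not normalised between arrays, as read from its values. Beside each intensity the deposited table gives a detection p-value, which per the file headers and the values ranks the probe among 798 negative control probes. Both were exported by the authors with GenomeStudio 2010.1, per the submitters' processing notes. The authors' processed values, also deposited, are linear intensities that were background-subtracted and quantile-normalised as judged from the values, with column medians of 37.0 to 38.1. The steps behind them are not given in the sources used here, and they served as an alternative with a floor of 16.

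The array median intensity ran from 64.1 to 250. It was lowest on chip 3, at 64.1 to 81.4, and highest on chip 5, at 193 to 250. The number of arrays limits the precision. The table holds 25697 probes, of which 23978 are listed with 1 gene symbol, 0 with several and 1719 with none; 23962 matched a mouse gene in the reference table by gene number. Gene names come from these tables, no genome build is named, and no coordinates are given.

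Intensities were background-corrected with the detection p-values, given an offset of 16, quantile-normalised and taken to log2 with neqc of limma 3.58.1 in R 4.3.3. A probe counted as detected in an array at a detection p under 0.01. Probes detected in at least 4 arrays were kept, which left 12482, of which 718 have no gene name and were used only as listed in the closing section. Of 2244 genes with several detected probes the brightest was used, which gave 8658 genes tested.

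Arrays of different chips with the same genotypes at the same positions were joined to 1 sample if at least 75% of them correlated best with their partner after group and chip were removed, with a median correlation above 0.3. Chips 6 and 7 met this with 11 of 12 arrays and a median correlation of 0.491, and no other chip pair did. The 6 pairs of arrays were averaged, which left 41 samples on 6 chip sets. In 2 of the 6 pairs 1 array had the Y-linked transcript Eif2s3y and the other had not, so these are separate embryos averaged into 1 sample; every array as its own replicate is among the alternatives. Whether each array holds 1 embryo or a pool is not given in the sources used here. By Xist and Eif2s3y, 21 arrays were female, 26 were male and 0 were mixed.

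All 5 genotypes were fitted together with limma's lmFit and eBayes, with chip set as a fixed effect and 31 residual degrees of freedom. The comparisons were MyoD-/- against wild type, the DnMaml;MyoD mutant against MyoD-/-, the Rbpj;MyoD mutant against MyoD-/-, MyoD+/- against wild type, and the Rbpj;MyoD against the DnMaml;MyoD mutant. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested; tests are two-sided. Changes are log2 fold changes adjusted for chip set, with the standard error (SE) of the fit; group levels are log2 intensities with the standard deviation (SD) over samples. Where a gene was undetected in every array of 1 group, the fold is given as "at least". It compares the mean of the other group, not adjusted for chip set, with the highest level that still counts as undetected. The adjusted p beside it comes from the fit. The median of its list is also given with such genes at that bound. For this median, genes whose mean in the other group gave no bound were set to no change. Genes undetected in both groups were left out of it. The list tests do not use the bounds.

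The comparisons, the alternatives, 24 gene lists and the rule for named genes were fixed before the data were examined. Named genes are Myod1, Rbpj and Maml1; the 8 largest rises and 8 largest falls among called genes in each comparison against MyoD-/- or of MyoD-/- with wild type; the 4 largest each way in the other comparisons; and up to 4 called members of each list with the lowest adjusted p, or the 1 member with the lowest p. Predicted genes were passed over among the largest changes. The lists cover Notch target genes, Notch pathway components, muscle progenitor markers, muscle differentiation genes, acetylcholine receptor and neuromuscular genes, basement membrane components, interstitial matrix components, matrix receptors and adhesion molecules, cell cycle genes, cell cycle inhibitors, Id and BMP or TGF-beta pathway genes, growth factor signalling genes, immediate early and dissociation stress genes, and hypoxia and glycolysis genes. The others hold markers of endothelial, leukocyte, erythroid, fibroblast, smooth muscle and pericyte, Schwann and neural crest, tendon and cartilage, adipocyte, neuronal and keratinocyte cells. The basement membrane and matrix receptor lists were drawn up knowing that work on this model had addressed adhesion of progenitors to the basal lamina.

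Lists were compared with all other genes by camera with a preset correlation of 0.01, adjusted over 115 tests of 23 lists in 5 comparisons. The keratinocyte list had 1 measured member and was not tested. Of the 115 tests 43 passed, and 15 passed with a correlation estimated from the residuals; the list p-values in the text are from the preset correlation unless said otherwise. Fry, which asks whether a list's genes move, on balance, one way, called 51, and its test for changes in either direction called 38.

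The fit was tested on simulated data, with 200 changed genes planted among the 8658. At a true log2 change of 1 it recovered 97% in MyoD-/- against wild type, 94% for the DnMaml;MyoD and 92.5% for the Rbpj;MyoD mutant, 79.1% in MyoD+/- against wild type and 82.1% between the double mutants. At a log2 change of 0.5 the shares were 61.2%, 58.2%, 56.7%, 28.4% and 31.3%. Alternatives covered the background correction, the normalization, the authors' values, the filters, the probe per gene, the chip term, the merging, the samples in the fit, sample weights, a fold threshold, the replicate numbers as a block, and the samples and chip sets left out. A covariate for Eif2s3y, the fit without the 3 arrays with the fewest detected probes, the fit of chip sets 4, 5 and 6+7 only, and leaving out each replicate of the groups with more than 5 were chosen after seeing the data. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 drew the plots.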

Results

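Gene expression was measured in muscle progenitor cells of mouse embryos at E17.5, sorted from back muscle as positive for Vcam-1, an adhesion molecule of muscle progenitors, and negative for the endothelial marker CD31, the blood cell marker CD45 and Sca1, a marker of interstitial mesenchymal cells. The genotypes were wild type (10 arrays, 9 samples), MyoD+/- (4 arrays, 3 samples) and MyoD-/- (18 arrays, 16 samples). A pair of double mutants lack MyoD and also interfere with Notch signalling. In the DnMaml;MyoD mutant (8 arrays, 7 samples) Pax3-driven Cre switches on DnMaml, a truncated Mastermind that blocks transcription by the Notch complex. In the Rbpj;MyoD mutant (7 arrays, 6 samples) the same Cre deletes Rbpj, the DNA-binding protein of that complex. Probes detected per array ranged from 8761 to 11561 in wild type, 10501 to 11505 in MyoD+/-, 9109 to 11768 in MyoD-/-, 9696 to 11530 in the DnMaml;MyoD and 9632 to 11819 in the Rbpj;MyoD mutant. Chip sets 1 and 2 hold wild type, MyoD-/- and DnMaml;MyoD samples, chip set 3 holds MyoD-/- and Rbpj;MyoD samples, and chip sets 4, 5 and 6+7 hold all 5 genotypes with 2 MyoD-/- samples and 1 of each other.

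Myod1, the muscle-determining transcription factor removed in the mutants, had a mean log2 level of 11.15 ± 0.25 (SD, n = 9) in wild type, 10.84 ± 0.11 (SD, n = 3) in MyoD+/- and 9.28 ± 0.20 (SD, n = 16) in MyoD-/-. The log2 change from wild type to MyoD-/- was -1.93 ± 0.10 (SE, adjusted p = 4.07e-16). Its probe was still detected in 47 of 47 arrays, and where the probe lies against the deleted part of the gene is not given in the sources used here. The double mutants had 9.26 ± 0.17 (SD, n = 7) with DnMaml and 8.97 ± 0.39 (SD, n = 6) without Rbpj. Myod1 fell further in the Rbpj;MyoD mutant than in MyoD-/- (-0.37 ± 0.12, adjusted p = 0.0241), a call lost without Rbpj;MyoD replicate 2 (adjusted p = 0.0768), replicate 5 (0.0501) or replicate 6-7 (0.12). Deletion of Rbpj itself could not be read, since its 3 probes were detected in 0 of 47 arrays. Maml1, the normal Mastermind gene, changed by 0.27 ± 0.11 in MyoD-/- against wild type (adjusted p = 0.0753), by -0.11 ± 0.12 in the DnMaml;MyoD mutant (0.624) and by -0.01 ± 0.13 in the Rbpj;MyoD mutant (0.986), the last 2 against MyoD-/-; it does not read the DnMaml transgene. Of the early progenitor factors, Pax3 was detected in 0 arrays, and Pax7 and Myf5 in 2 of 47 each.

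**Figure D1:**
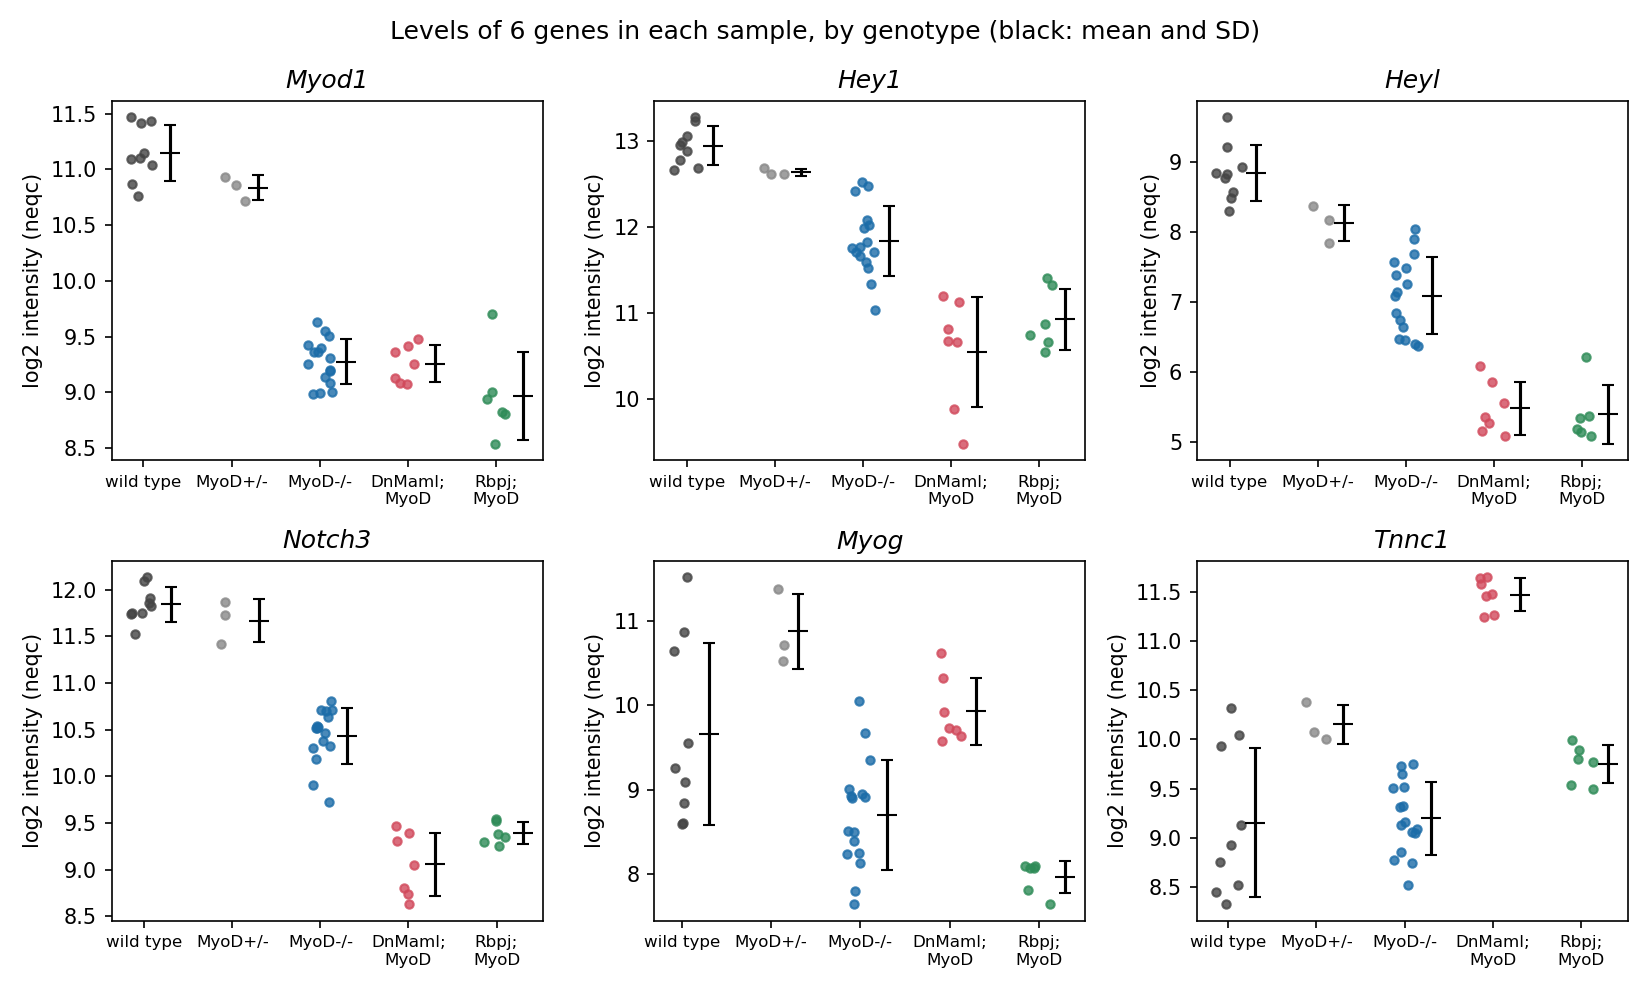
Log2 intensity of Myod1, Hey1, Heyl, Notch3, Myog and Tnnc1 in each sample by genotype; points are samples and black marks are the mean and SD. Myod1 falls from 11.15 in wild type to 9.28 in MyoD-/-, Hey1, Heyl and Notch3 fall again in both double mutants, and Myog and Tnnc1 are highest among the mutants with DnMaml.

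The comparison of MyoD-/- with wild type asks what progenitors express once MyoD is lost (n = 16 and 9 samples). Transcripts of Notch target genes were lower. Of 7 measured 0 rose, 5 fell (6 adjusted over the list alone) and 2 did not pass. They include the Notch-induced repressor genes Heyl (-1.86 ± 0.18) and Hey1 (-1.20 ± 0.13) and the receptor gene Notch3 (-1.46 ± 0.12), with a list median of -1.20 (adjusted p = 1.5e-07) and medians of -1.17 to -0.95 in the 5 chip sets that hold both genotypes. Genes of the neuromuscular synapse fell too, 6 of 9 over all genes and adjusted over the list alone, with Rapsn, which clusters acetylcholine receptors, at -1.66 ± 0.11 and the receptor subunit Chrng at -0.85 ± 0.11. The median of the 9 was -0.53, or -0.46 at the bounds (adjusted p = 8.96e-06; chip-set medians -0.64 to -0.42). Within the list, the receptor subunit Chrna1 (-0.94 ± 0.16) fell by different amounts on early and late chips.

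Among the single genes with the largest falls were Ptprv, a receptor phosphatase (-2.55 ± 0.31, detected in 14 of 18 MyoD-/- arrays), Mycl, a Myc family factor (-1.92 ± 0.12), Sgca, a sarcoglycan of the dystrophin complex (-1.76 ± 0.14), the kinase Prkcb (-1.76 ± 0.11, detected in 2 of 18 MyoD-/- arrays) and titin, Ttn (-1.67 ± 0.16, in 12 of 18). Calcr, the calcitonin receptor, was detected in 0 of 18 MyoD-/- and 9 of 10 wild-type arrays and was at least 1.44-fold lower (adjusted p = 2.18e-14; -0.72 ± 0.14 by a second probe). Large rises were in the neuropeptide gene Nmu (2.42 ± 0.27), the chemokine Ccl5 (2.37 ± 0.52), the adhesion gene Kirrel3 (2.25 ± 0.19), Rgs17 (2.14 ± 0.21) and the AP-1 factor Fosl1 (2.02 ± 0.21). Wild-type arrays detected Nmu in 7 of 10, Ccl5 and Kirrel3 in 5 of 10 each and Rgs17 in 9 of 10. Ppl, a desmosomal linker, Stac2 and Sprr2k were detected in 0 wild-type arrays and were at least 3.08-fold, 2.42-fold and 2.001-fold higher (adjusted p = 1.69e-12, 4.73e-11 and 6.44e-10). A second Ppl probe changed by 0.19 ± 0.14 only.

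Muscle differentiation genes went both ways. Of 27 measured, 4 rose, 11 fell (4 and 12 adjusted over the list alone) and 12 did not pass. The calcium release channel Ryr1 (-1.39 ± 0.13), slow troponin Tnnt1 (-0.96 ± 0.10) and Ttn fell, while the perinatal myosin Myh8 rose by 1.60 ± 0.10. The list median was -0.28 (adjusted p = 0.0102), and adjusted p = 0.392 with an estimated correlation and 7.11e-03 by fry. Chip-set medians ran from -1.24 to 0.05, with 2 above 0 and 3 below, so the pooled fall was not shared by all chip sets. Wild-type samples on chip sets 1 and 2 had the troponin gene Tnnc1 at 8.328 to 9.135. Those on chip sets 4, 5 and 6+7 had it at 9.929 to 10.317. In MyoD-/- samples the ranges were 8.52 to 9.31 and 8.861 to 9.735. Of 15 progenitor markers 5 rose and 2 fell (6 and 3 adjusted over the list alone), with a median of 0.27 (adjusted p = 0.63). The phagocytic receptor Megf10 fell (-0.92 ± 0.08) and the syndecan Sdc4 rose (0.59 ± 0.12). Vcam1 rose as well (0.70 ± 0.11), but it is the marker the cells were sorted on.

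Basement membrane genes fell: 0 of 14 rose, 8 fell (9 adjusted over the list alone) and 6 did not pass, with agrin, Agrn, at -0.63 ± 0.09, the laminin chain Lamc1 at -0.54 ± 0.10 and the collagen Col4a2 at -0.49 ± 0.09. The median was -0.28 (adjusted p = 9.55e-04; chip-set medians -0.44 to -0.24), and adjusted p = 0.11 with an estimated correlation and 5.61e-06 by fry. Of 16 matrix receptors 1 rose and 7 fell (2 and 8 adjusted over the list alone), among them dystroglycan, Dag1 (-1.06 ± 0.10), and the laminin receptor Itga7 (-0.79 ± 0.11). Their median was -0.24, -0.18 at the bounds and -0.12 with arrays scaled to a common median (adjusted p = 7.88e-03 in the main fit, chip-set medians -0.42 to -0.07), and adjusted p = 0.0765 with an estimated correlation and 1.16e-07 by fry. Interstitial matrix genes had a median of 0.04, with 2 of 18 higher and 1 lower (4 and 1 adjusted over the list alone; adjusted p = 0.582). Both rises, Col5a3 (0.53 ± 0.15) and Thbs1 (0.97 ± 0.30), had the same sign in only 3 of 5 chip sets and turned to -0.133 and -0.357 on chip sets 4, 5 and 6+7 only. Thbs1 lost its call without wild-type replicate 1 (adjusted p = 0.0502) or 4 (0.0522).

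Among 18 cell cycle genes 0 rose and 5 fell, also adjusted over the list alone, with the G1/S cyclin Ccne1 at -0.92 ± 0.16 and the mitotic genes Cdc20 at -0.55 ± 0.11 and Birc5 at -0.46 ± 0.10. The median was -0.17 (adjusted p = 0.0333, chip-set medians -0.28 to -0.03), and adjusted p = 0.313 with an estimated correlation and 2.45e-03 by fry. With arrays scaled to a common median it shrank to -0.046. Of 10 cell cycle inhibitors 1 rose and 2 fell (1 and 3 adjusted over the list alone; adjusted p = 0.173), with the retinoblastoma genes Rb1 at -0.65 ± 0.12 (-0.27 ± 0.13 by a second probe) and Rbl1 at -0.60 ± 0.12. Notch pathway components had 0 higher and 5 lower of 16 (2 and 6 adjusted over the list alone), among them the ligand Dll1 (-0.85 ± 0.12), the receptor Notch1 (-0.85 ± 0.09) and the glycosyltransferase Mfng (-1.54 ± 0.19, detected in 7 of 18 MyoD-/- arrays). Their median of -0.07 turned to 0.004 with arrays scaled to a common median (adjusted p = 0.0361, and adjusted p = 0.0724 with an estimated correlation and 1.04e-07 by fry). Growth factor signalling genes had 1 of 17 higher, the receptor Fgfr1 (0.70 ± 0.11), and 5 lower, such as Igfbp5 (-0.53 ± 0.09), with 1 and 6 adjusted over the list alone and a median of -0.15 (adjusted p = 0.132). Of 14 Id and BMP or TGF-beta genes 1 rose and 1 fell (1 and 0 adjusted over the list alone; median 0.03, adjusted p = 0.797).

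Among markers of other cell types 1 of 8 fibroblast markers rose, Osr2 (1.08 ± 0.11), and 0 of 3 erythroid and 0 of 2 leukocyte markers passed, with adjusted p = 0.591, 0.431 and 0.842 for the lists and the same counts adjusted over the list alone. The fibroblast median was -0.15 although the mean and the test pointed up. Single markers of other cell types were called as well, Gap43 and Pparg higher and Tagln, Lpl, Acta2, Egfl7 and Ngfr lower. Their lists are in the closing section. In total 1914 of 8658 genes were called, 929 higher and 985 lower, and 150 of these changed by at least 1 on the log2 scale. With arrays scaled to a common median the split was 802 higher and 370 lower of 1172, and without chip set 2 the count was 885. Scaling to a common median also ended the calls of Col4a2, Lamc1, Cdc20 and Birc5. On chip sets 4, 5 and 6+7 only, which hold fewer samples, Ccl5, Ccne1, Cdc20, Birc5, Rbl1, Fgfr1, Pparg and Ngfr lost the call. Of 70 called named genes, 62 had the same sign in all 5 chip sets.

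**Figure D2:**
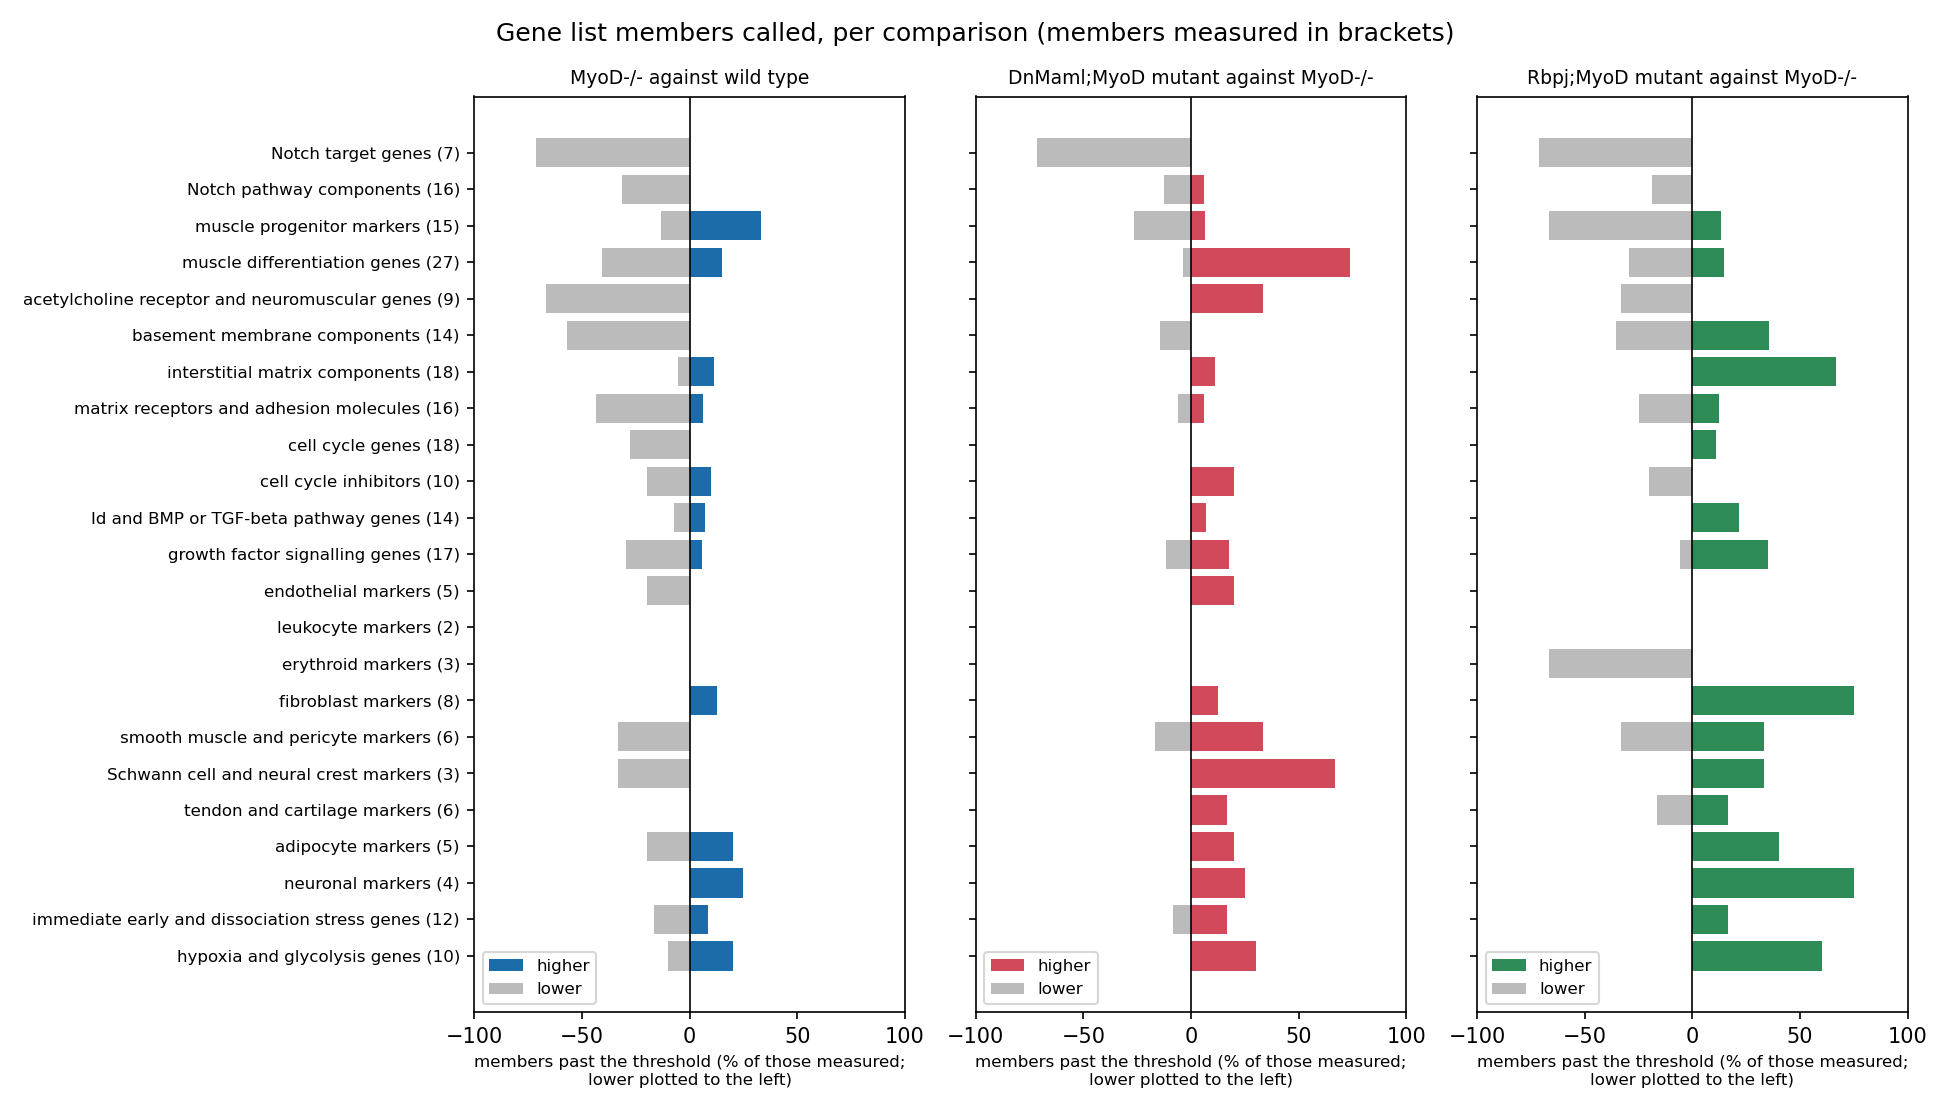
Percentage of each list's measured members that were called higher (coloured, to the right) or lower (grey, to the left) in MyoD-/- against wild type and in each double mutant against MyoD-/-, for 23 lists. Muscle differentiation genes are mostly higher in the DnMaml;MyoD mutant, with 20 of 27, and fibroblast and interstitial matrix genes mostly higher in the Rbpj;MyoD mutant, with 6 of 8 and 12 of 18.

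The DnMaml;MyoD mutant against MyoD-/- asks what Notch-driven transcription adds in progenitors without MyoD (n = 7 and 16 samples). Muscle differentiation genes rose: 20 of 27 were higher, 1 was lower and 6 did not pass, with the same counts adjusted over the list alone. Among them were the sarcomere genes Tnnc1 (2.42 ± 0.17, adjusted p = 1.75e-12) and Tnni1 (2.27 ± 0.22), the calcium store gene Casq2 (1.92 ± 0.23) and the myosin light chain Myl4 (1.20 ± 0.13). MyoD-/- arrays detected Tnni1 in 4 of 18 and Casq2 in 2 of 18. Their median was 0.997 (adjusted p = 1.14e-27), or 0.62 to 1.19 in 5 chip sets. Notch target genes fell further, 0 higher and 5 lower of 7 (6 adjusted over the list alone): Notch3 by -1.33 ± 0.13, Hey1 by -1.16 ± 0.14 and Dtx4 by -0.79 ± 0.10. Heyl was detected in 0 of 8 DnMaml;MyoD arrays and was at least 1.37-fold lower (adjusted p = 5.03e-07). The target list had a median of -0.79, or -0.61 at the bounds (adjusted p = 1.53e-10; chip-set medians -1.03 to -0.60).

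Progenitor markers fell in the same samples, with 1 of 15 higher and 4 lower (2 and 8 adjusted over the list alone) and a median of -0.32, or -0.31 at the bounds (adjusted p = 1.3e-03; chip-set medians -0.60 to -0.18). The repressor Msc fell by -0.70 ± 0.07, the caveolin Cav1 by -0.47 ± 0.11 and the chemokine receptor Cxcr4 by -0.65 ± 0.14. Cxcr4 lost its call without the chip term. The fourth fall, Calcr, lies between background values, since it was detected in 0 of 8 DnMaml;MyoD and 0 of 18 MyoD-/- arrays. Of 9 neuromuscular genes 3 rose and 0 fell (4 and 1 adjusted over the list alone): Chrna1 by 1.34 ± 0.17, Chrng by 0.89 ± 0.12 and Dok7 by 0.72 ± 0.17, the last detected in 5 of 8 and 2 of 18 arrays. Their median was 0.23 but 0.00 at the bounds (adjusted p = 0.0188), and adjusted p = 0.0535 with an estimated correlation and 6.65e-06 by fry. This 0.00 is the value set for a gene without a bound, not a measured change. Chip-set medians ran from -0.02 to 0.51.

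Other large rises were in Mbp, myelin basic protein (2.45 ± 0.27, detected in 6 of 18 MyoD-/- arrays; 1.39 to 3.06 over the alternatives, adjusted p up to 0.0844), the endothelin receptor Ednrb (2.31 ± 0.25), the matrilin Matn4 (1.97 ± 0.32, in 13 of 18), the calcium-binding Hrc (1.97 ± 0.22, in 3 of 18) and the muscle form of a respiratory subunit, Cox6a2 (1.94 ± 0.31, in 12 of 18). Mbp and the neurotrophin receptor Ngfr (0.92 ± 0.19) are Schwann cell and neural crest markers, of which 2 of 3 measured rose and 0 fell, also adjusted over the list alone (median 0.92, adjusted p = 4.24e-04, chip-set medians 0.57 to 1.39). Of the 10 genes fixed for this list, S100b, Foxd3 and Cdh19 were on the array but failed the detection filter, and 4 were not on it. Large falls were in the netrin Ntn5 (-1.64 ± 0.17), Ptprv (-1.58 ± 0.33, detected in 5 of 8 and 14 of 18 arrays; -1.88 to -0.91 over the alternatives, adjusted p up to 0.191) and Esm1 (-1.37 ± 0.30). Bpifb5 was detected in 0 of 8 DnMaml;MyoD arrays and was at least 1.66-fold lower (adjusted p = 1.35e-06). The falls of Ccng2 (-1.34 ± 0.33) and Mip (-1.18 ± 0.23, in 3 of 8) had the opposite sign in 1 of 5 chip sets each.

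Of 14 basement membrane genes 0 rose and 2 fell (3 adjusted over the list alone), Col4a2 (-0.48 ± 0.10) and Col18a1 (-0.29 ± 0.07), with a median of -0.03 (-0.06 at the bounds; adjusted p = 0.328). Both lost the call with arrays scaled to a common median. Of 18 interstitial matrix genes 2 rose, such as Col5a3 (0.66 ± 0.16), and 0 fell, also adjusted over the list alone (median 0.20, adjusted p = 0.0188), with adjusted p = 0.426 with an estimated correlation and 0.0928 by fry and chip-set medians of -0.11 to 0.54. Among 16 matrix receptors Itga7 fell (-0.94 ± 0.12) and 1 rose, with 3 higher and 2 lower adjusted over the list alone. The median of 0.04, or 0.03 at the bounds, turned to -0.02 with arrays scaled to a common median, and the test pointed down (adjusted p = 0.842). None of 18 cell cycle genes was called by limma, 0 over all genes and 0 adjusted over the list alone, and the camera test gave adjusted p = 0.961. Of 10 cell cycle inhibitors 2 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.348), and of 16 Notch components 1 rose, Dll1 (0.58 ± 0.13), and 2 fell, among them Notch1 (-0.46 ± 0.10), with 1 and 3 adjusted over the list alone (adjusted p = 0.274). Growth factor genes had 3 of 17 higher and 2 lower (5 and 3 adjusted over the list alone), with the insulin-like growth factor binding protein Igfbp2 at 0.86 ± 0.16 and the ETS factor Etv4 at 1.06 ± 0.21 (detected in 2 of 18 MyoD-/- arrays), a median of -0.12 and a test pointing up (adjusted p = 0.707). Bmp7 was the 1 of 14 Id and BMP or TGF-beta genes that rose (0.81 ± 0.14), 1 adjusted over the list alone (adjusted p = 0.494).

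Fibroblast markers stood beside these groups with 1 of 8 higher and 0 lower (2 adjusted over the list alone), a median of 0.25 and adjusted p = 0.0361, but adjusted p = 0.318 with an estimated correlation and 0.0583 by fry; chip-set medians ran from 0.00 to 1.11. Its called member Dcn, a matrix proteoglycan (0.56 ± 0.18, adjusted p = 0.0452), lost its call without DnMaml;MyoD replicate 1, 3, 4, 5, 6 or 7-8 or MyoD-/- replicate 2, 5, 6, 11, 13, 14 or 15-17 (adjusted p = 0.0512 to 0.128). Of 3 erythroid and 2 leukocyte markers 0 were called, also adjusted over the list alone (adjusted p = 0.918 and 0.946). In total 763 genes were called, 467 higher and 296 lower, of which 99 changed by at least 1. The count fell to 353 with arrays scaled to a common median, 444 without chip set 2 and 391 without chip set 5. Of the genes named here, Col5a3 and Dcn also lost the call with arrays scaled to a common median, and Dll1, Col4a2 and Dcn without the chip term. On chip sets 4, 5 and 6+7 only Ptprv, Ccng2, Mip, Col4a2 and Col18a1 lost it, and with the replicate block Mbp, Cxcr4, Col4a2, Igfbp2 and Notch1. In all, 50 of 57 called named genes had the same sign in all 5 chip sets.

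The Rbpj;MyoD mutant against MyoD-/- puts the same question with the DNA-binding partner of Notch removed (n = 6 and 16 samples). Notch target genes fell again, 0 higher and 5 lower of 7, also adjusted over the list alone: Notch3 by -1.10 ± 0.14 and Hey1 by -0.97 ± 0.15. Heyl was detected in 0 of 7 Rbpj;MyoD arrays and was at least 1.33-fold lower (adjusted p = 2.75e-08). The list median was -0.97, or -0.42 at the bounds (adjusted p = 1.92e-05; chip-set medians -0.99 to -0.80). Progenitor markers fell here too, with 2 of 15 higher and 10 lower (2 and 11 adjusted over the list alone). Against this, the list member Meox2, a homeobox gene, rose by 2.11 ± 0.28 (adjusted p = 7.37e-07, detected in 13 of 18 MyoD-/- arrays). Msc (-0.82 ± 0.08), Megf10 (-0.83 ± 0.09), Cav1 (-0.92 ± 0.12) and Cxcr4 (-1.11 ± 0.15) were among the falls, with a list median of -0.58, or -0.39 at the bounds (adjusted p = 2.54e-04; chip-set medians -0.72 to -0.33). Vcam1, the sort marker, fell by -0.58 ± 0.12. Calcr, counted among the falls, was detected in 0 of 7 Rbpj;MyoD and 0 of 18 MyoD-/- arrays.

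Muscle differentiation genes went both ways here, with 4 of 27 higher and 8 lower (4 and 9 adjusted over the list alone), and their median of -0.14, or -0.11 at the bounds, did not pass (adjusted p = 0.246). Ttn (1.38 ± 0.19) and Tnnt1 (0.78 ± 0.11) rose, while Myh8 (-0.75 ± 0.12) and the caveolin Cav3 (-1.42 ± 0.13, detected in 2 of 7 Rbpj;MyoD arrays) fell. Neuromuscular genes fell, 0 higher and 3 lower of 9 (1 and 4 adjusted over the list alone), with Rapsn at -0.81 ± 0.13, the receptor kinase Musk at -1.41 ± 0.26 (-0.67 ± 0.22 by a second probe) and Chrnb1 at -0.62 ± 0.13. Their median was -0.23 (adjusted p = 0.0341; chip-set medians -0.39 to -0.26), and adjusted p = 0.0763 with an estimated correlation and 3.45e-06 by fry.

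Genes of connective tissue rose. Of 18 interstitial matrix genes 12 rose and 0 fell (14 and 0 adjusted over the list alone): collagen I, Col1a1, by 1.66 ± 0.29, Thbs2 by 1.65 ± 0.19 and Col5a2 by 0.95 ± 0.17. The median was 0.69 (adjusted p = 5.97e-08; chip-set medians 0.46 to 1.06), and adjusted p = 0.0765 with an estimated correlation and 7.4e-06 by fry. Of 8 fibroblast markers 6 rose and 0 fell (7 and 0 adjusted over the list alone), with the receptor Pdgfra at 1.94 ± 0.36, Col14a1 at 1.84 ± 0.23, Lum at 1.55 ± 0.33 and Dcn at 1.17 ± 0.19, and a median of 1.25 (adjusted p = 1.87e-06; chip-set medians 0.92 to 1.84). Basement membrane genes divided into 5 higher and 5 lower of 14 (6 and 6 adjusted over the list alone), the nidogen Nid1 (1.02 ± 0.16) against Col18a1 (-0.57 ± 0.08), with a median of -0.03, or -0.11 at the bounds, and a test pointing up (adjusted p = 0.911). Of 16 matrix receptors 2 rose and 4 fell, also adjusted over the list alone: Itgb5 rose by 0.71 ± 0.11, while Itga7 (-1.50 ± 0.13), Sgca (-1.20 ± 0.16, and -0.40 ± 0.13 and -1.40 ± 0.17 by other probes) and Mcam (-1.08 ± 0.10) fell. Their median of 0.03, 0.00 at the bounds, changed sign between scalings, and the test pointed down (adjusted p = 0.338). The 0.00 comes from setting genes without a bound to no change.

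Growth factor signalling genes had 6 of 17 higher and 1 lower (6 and 2 adjusted over the list alone), with Etv4 at 2.68 ± 0.22 (detected in 2 of 18 MyoD-/- arrays), Igfbp4 at 0.84 ± 0.11 and the ligand Pdgfa at -0.75 ± 0.12. The test gave adjusted p = 0.0341, and adjusted p = 0.0957 with an estimated correlation and 2.63e-06 by fry, while the median of 0.05 turned to -0.03 with arrays scaled to a common median. Follistatin, Fst (1.52 ± 0.30), and Bmp7 (0.70 ± 0.15) were among 3 of 14 Id and BMP or TGF-beta genes that rose; 0 fell (4 and 0 adjusted over the list alone; adjusted p = 0.252). Cell cycle genes had 2 of 18 higher and 0 lower (1 and 0 adjusted over the list alone; adjusted p = 0.169), with cyclin D1, Ccnd1, at 0.73 ± 0.15, a call lost with arrays scaled to a common median. Of 10 inhibitors 0 rose and 2 fell, also adjusted over the list alone, Gadd45a (-0.73 ± 0.13) and Rb1 (-0.72 ± 0.14). The list did not pass (adjusted p = 0.591). Notch components had 0 higher and 3 lower of 16 (1 and 3 adjusted over the list alone; adjusted p = 0.532). Of these the ligand Jag2 was detected in 0 of 7 Rbpj;MyoD arrays and was at least 1.13-fold lower (adjusted p = 6.11e-03), and Dll1 fell by -0.45 ± 0.14, a call lost without Rbpj;MyoD replicate 3 (adjusted p = 0.0655) or 6-7 (0.132).

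The largest single rises were in Cntnap4, a neurexin relative (2.88 ± 0.20, adjusted p = 4.23e-13, and 1.40 ± 0.14 by a second probe), Etv4, the platelet chemokine gene Pf4 (2.53 ± 0.20), Ebf2, a factor of brown adipocyte precursors (2.27 ± 0.38), the homeobox gene Meox2 (2.11 ± 0.28), tenascin-X, Tnxb (2.11 ± 0.21), and the annexin Anxa3 (2.09 ± 0.16). MyoD-/- arrays detected Cntnap4 in 8 of 18, Pf4 in 2, Ebf2 in 9 and Meox2 and Ctsc in 13 each. Ctsc also rose (2.11 ± 0.57, and 1.21 ± 0.41 and 1.10 ± 0.29 by other probes), with the same sign in 3 of 4 chip sets. The largest falls were in the peptide hormone gene Cck (-2.39 ± 0.17), Dpysl5 (-2.15 ± 0.16, detected in 3 of 7 Rbpj;MyoD arrays), the transcription factor Sim2 (-2.14 ± 0.19), Ptprv (-2.11 ± 0.36, in 2 of 7), Tmem255a (-2.10 ± 0.15), Ntn5 (-2.09 ± 0.18) and Chodl (-1.90 ± 0.16). Alas2, the first enzyme of heme synthesis in red cells, fell by -2.09 ± 0.31 (in 3 of 7), and alpha-globin, Hba-a1, by -1.66 ± 0.24. With them 0 of 3 erythroid markers rose and 2 fell (3 adjusted over the list alone; median -1.66, adjusted p = 1.78e-03, chip-set medians -2.08 to -1.09), and adjusted p = 0.0932 with an estimated correlation and 1.78e-05 by fry.

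In total 1742 genes were called, 883 higher and 859 lower, and 327 changed by at least 1, of which 237 were higher. The count was 1065 with arrays scaled to a common median, with 490 higher and 575 lower, 1049 without chip set 5, 1146 without Rbpj;MyoD replicate 5 and 3668 with sample weights. Dll1 and Myod1 also lost the call with arrays scaled to a common median, and Ctsc, Dll1 and Myod1 without the chip term. With the replicate block Ctsc, Dll1, Alas2, Chrnb1, Gadd45a and Rapsn lost it, and on chip sets 4, 5 and 6+7 only Ctsc and Jag2. Of 79 called named genes, 75 had the same sign in all 4 chip sets that hold both genotypes.

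Both double mutants interfere with the Notch complex, and their changes overlapped. Of the genes called against MyoD-/-, 441 moved the same way in both, 253 up and 188 down, where independent lists of the same sizes would share 47.6 and 29.4. A further 305 were called only with DnMaml and 1284 only without Rbpj, counts that do not test a difference. Among the shared falls were Notch3, Hey1, Heyl, Dtx4, Msc, Cxcr4, Ptprv, Ntn5 and Itga7, and among the shared rises Etv4, Ngfr, Igfbp2, Bmp7 and Gap43. The log2 changes correlated across genes with r = 0.581, while simulated unchanged groups that share their controls gave a mean of 0.183 and a highest of 0.239 in 100 simulations. The simulated genes varied independently of each other, so the spread of r over the simulations may be too narrow and 0.239 is no firm ceiling. Genes are not independent replicates. With the MyoD-/- samples divided into separate controls for each mutant, in 20 splits, a median of 246 genes moved the same way and r was 0.511.

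The double mutants differed in muscle differentiation genes, tested as the Rbpj;MyoD minus the DnMaml;MyoD mutant (n = 6 and 7 samples). Only chip sets 4, 5 and 6+7 hold both, with 1 sample of each. The other samples are compared through the MyoD-/- samples and the chip term. For muscle differentiation, neuromuscular, erythroid, fibroblast and growth factor signalling genes the median of the fit was larger in size than that of every chip set. Of 27 muscle differentiation genes 0 were higher and 19 lower without Rbpj, also adjusted over the list alone, with a median of -1.30, or -1.19 at the bounds (adjusted p = 1.33e-31, chip-set medians -1.06 to -0.94). The slow troponin Tnni1 differed by -2.69 ± 0.29 (detected in 2 of 7 Rbpj;MyoD arrays), Myog, myogenin, by -2.48 ± 0.29 (-0.86 ± 0.32 by a second probe), Tnnc1 by -2.12 ± 0.22 and Cav3 by -1.65 ± 0.17 (also in 2 of 7). Where few arrays detected a gene, the size of its change rests on background values. Mymk, the fusion factor myomaker, was detected in 8 of 8 DnMaml;MyoD and 0 of 7 Rbpj;MyoD arrays and was at least 2.64-fold lower without Rbpj (adjusted p = 2.84e-06). Neuromuscular genes had 0 higher and 3 lower of 9 (5 adjusted over the list alone), among them Chrna1 (-1.81 ± 0.22) and Chrng (-1.12 ± 0.15), with a median of -0.70, or -0.43 at the bounds (adjusted p = 4.86e-07; chip-set medians -0.67 to -0.50). Kcnk13, a potassium channel (-2.63 ± 0.23, in 4 of 7 Rbpj;MyoD arrays), and Ednrb (-2.50 ± 0.33) were also much lower without Rbpj. Higher were Etv4 (1.62 ± 0.27), Gsdmc2 (1.63 ± 0.39, in 5 of 8 DnMaml;MyoD arrays), Fpr2 (1.77 ± 0.43, in 1 of 8) and Ccng2 (1.58 ± 0.43). Fpr2 lost its call without Rbpj;MyoD replicate 5 (adjusted p = 0.0605). Ccng2 lost it without Rbpj;MyoD replicate 4, 5 or 6-7 or DnMaml;MyoD replicate 1, 3 or 5 (adjusted p = 0.0587 to 0.11).

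In 17 genes the mutants moved in opposite directions from MyoD-/-, up with DnMaml and down without Rbpj. They were chosen by these opposite calls, so a test of their difference nearly restates the choice. They include Myog (1.38 and -1.10), the cardiac actin Actc1 (0.86 and -0.48), Mycl (0.46 and -1.33), Kcnk13 (0.83 and -1.80) and Rb1 (0.45 and -0.72). The rise of Rb1 with DnMaml lost its call without DnMaml;MyoD replicate 1 (adjusted p = 0.067) or 6 (0.051). Of the others, Acta2 lost a call without DnMaml;MyoD replicate 3 (0.0694) or Rbpj;MyoD replicate 5 (0.0581) and Dll1 without Rbpj;MyoD replicate 3 or 6-7. Notch target genes did not separate the mutants: 0 of 7 differed, also adjusted over the list alone, with a median of 0.19, or 0.21 at the bounds (adjusted p = 0.582), which does not show that both act alike. Fibroblast markers were higher without Rbpj, 1 of 8 over all genes, Col14a1 (1.19 ± 0.28), and 6 adjusted over the list alone, with a median of 0.91 (adjusted p = 3.31e-05, chip-set medians 0.585 to 0.826) and adjusted p = 0.0631 with an estimated correlation and 1.61e-03 by fry. Interstitial matrix genes had 1 of 18 higher, Thbs2 (1.02 ± 0.24), and 5 adjusted over the list alone (median 0.38, adjusted p = 3.17e-06), with adjusted p = 0.142 with an estimated correlation and 8.03e-03 by fry. Erythroid markers had 2 of 3 lower, also adjusted over the list alone (median -1.80, adjusted p = 4.74e-05; chip-set medians -1.70 to -0.79). Progenitor markers, tested between the double mutants, did not pass as a list, with 1 of 15 higher and 1 lower (1 and 2 adjusted over the list alone), a median of -0.22 (adjusted p = 0.0778, chip-set medians -0.29 to -0.09), and adjusted p = 0.162 with an estimated correlation and 8.42e-03 by fry. Growth factor genes had 2 of 17 higher and 0 lower (2 and 1 adjusted over the list alone), with a median of 0.18 (adjusted p = 8.86e-03, chip-set medians 0.03 to 0.13). In total 341 genes differed, 138 higher and 203 lower without Rbpj, and 146 by at least 1. The count was 192 with arrays scaled to a common median, where Col14a1 and Thbs2 lost the call, 71 with only these genotypes in the fit, where Etv4, Gsdmc2, Fpr2, Ccng2, Col14a1, Thbs2, Alas2 and Hba-a1 lost it, 193 without chip set 6+7 and 210 without Rbpj;MyoD replicate 5. Of 34 called named genes, 33 had the same sign in all 3 chip sets.

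**Figure D3:**
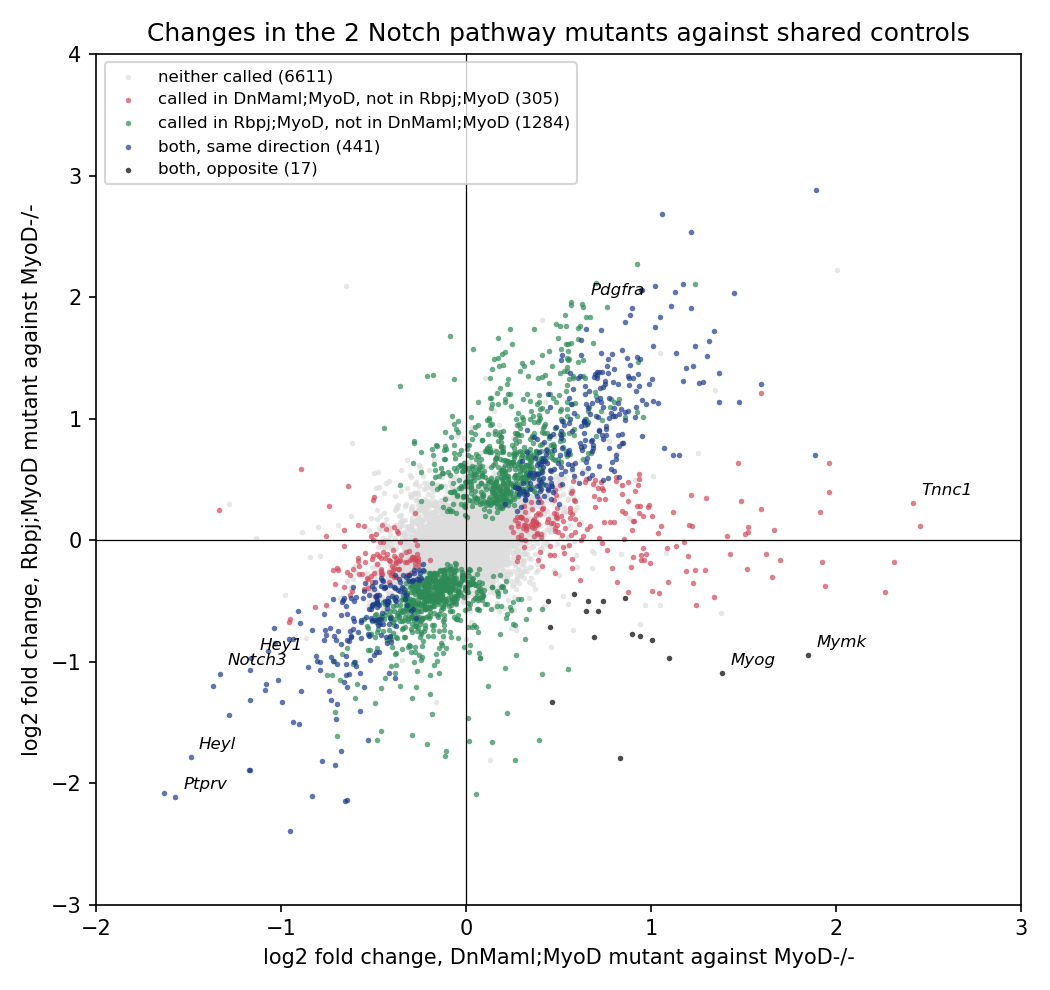
Log2 fold change against MyoD-/- of each gene in the DnMaml;MyoD mutant (x axis) and the Rbpj;MyoD mutant (y axis), coloured by where it was called. The 441 genes called in both the same way lie along the diagonal, with Notch3 and Heyl low in both, and Myog and Mymk lie at the lower right among the 17 called in opposite directions.

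MyoD+/- against wild type asks whether 1 copy of the gene is enough (n = 3 and 9 samples). Only chip sets 4, 5 and 6+7 hold both genotypes, with 1 sample of each. The other wild-type samples enter through the chip term. Myod1 changed by -0.29 ± 0.17 (adjusted p = 1), and limma called 0 genes; 314 had an unadjusted p under 0.05, where 433 are expected by chance. No list had a member called over all genes. Muscle differentiation genes had a median of 0.36 (adjusted p = 2.84e-09), with adjusted p = 0.0631 with an estimated correlation and 0.0448 by fry and chip-set medians of -0.12 to 0.23. The median of the fit lay above that of every chip set, and the chip sets differed in sign, so no rise is shown within chips. Tendon and cartilage markers, which belong to another cell type, had a median of 1.40, or 0.36 at the bounds (adjusted p = 2.04e-06), with 3 of 6 higher adjusted over the list alone. Chip-set medians were -0.04 to 1.37, so here too the median of the fit lay above that of every chip set, with 1 set below 0. The cartilage matrilin Matn1 stood at 2.64 ± 0.59 (adjusted p = 0.241). It was detected in only 2 of 4 MyoD+/- and 1 of 10 wild-type arrays, so this size rests on background values. Interstitial matrix genes had a median of 0.25 (adjusted p = 4.74e-05) and adjusted p = 0.201 with an estimated correlation and 0.157 by fry. Notch target genes had a median of -0.17 (adjusted p = 0.0341) and adjusted p = 0.157 with an estimated correlation and 0.0825 by fry. The fit recovered 28.4% of simulated changes of 0.5 on the log2 scale in this comparison, so changes of that size were mostly not detectable.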

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

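The tests of a lower share of muscle progenitors, of the chips for the muscle differentiation pattern and with Eif2s3y as a covariate were chosen after the result was seen; the other tests here were planned.

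Fibroblast markers were higher in the Rbpj;MyoD mutant than in MyoD-/-, with 6 of 8 called and abundant ones among them: Dcn stood at 14.63 ± 0.26 (SD, n = 6) against 13.43 ± 0.53 (n = 16), and Lum at 12.60 ± 0.36 against 11.24 ± 0.90. Chips as the whole cause were argued against, since the lowest mean change of the list in a chip set was 1.112. A lower share of progenitors was tested by whether the markers of every other cell type rose alike. Of these lists 1 fell, the erythroid markers, with 2 of 3 members called lower. As a list they had adjusted p = 0.0932 with an estimated correlation and 1.78e-05 by fry. These 3 genes cannot decide the question, since fibroblasts in the sorted fraction would themselves lower the share of progenitors. Progenitor markers fell, with chip-set medians of -0.723 to -0.328, as did the sort marker Vcam1, so a lower share stays open. Fibroblasts in the sorted fraction may account for the pattern and stay open: 0 members of the fibroblast or interstitial matrix lists fell, although the sort against Sca1 should remove such cells, and MyoD-/- arrays detected each of the 8 markers in at least 7 of 18 arrays. A change of the progenitors themselves towards connective tissue expression after loss of Rbpj also stays open, since no test here separates it from admixture.

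Muscle differentiation genes were higher in the DnMaml;MyoD than in the Rbpj;MyoD mutant, with 19 of 27 called. Chips were argued against as the whole cause, since the highest median difference in a chip set was -0.942 (Rbpj;MyoD minus DnMaml;MyoD). A different balance of female and male embryos was argued against too, since Eif2s3y was detected in 5 of 8 DnMaml;MyoD and 4 of 7 Rbpj;MyoD arrays. With shares so alike the Eif2s3y level as a covariate could hardly move the median, which stayed at -1.283. A varying share of differentiated muscle cells among the sorted DnMaml;MyoD cells may account for it and stays open: 20 members rose in that mutant against MyoD-/- and 1 fell, fewer than the 2 set as the limit, although that fall, of the myosin gene Myh8, runs against it. The most abundant members stood at 14.05 (Myl1) and 14.02 (Actc1) with DnMaml, the sort for Vcam-1 should remove differentiated cells, and each of the 27 was detected in at least 2 of 18 MyoD-/- arrays, so higher transcription in the progenitors stays open too.

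The mean log2 level of muscle differentiation genes in DnMaml;MyoD replicate 4 was 10.111, below the 10.25 to 10.345 of the other samples of its genotype. The mean of fibroblast markers in DnMaml;MyoD replicate 6 was 11.378, above the 10.285 to 10.753 of the others. The mean of neuronal markers in wild-type replicate 4 was 8.65, above the 7.558 to 7.85 of the others. Heyl stood at 6.209 in Rbpj;MyoD replicate 3 and at 5.084 to 5.369 in the others. Calcr stood at 5.009 in DnMaml;MyoD replicate 7-8 and at 4.737 to 4.852 in the others. Heyl was detected in 0 of 7 Rbpj;MyoD and Calcr in 0 of 8 DnMaml;MyoD arrays, so these last values are differences within the background and show no expression. These 5 samples far from their group came from 102 tests, in which 5.1 are expected by chance.

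The double mutants differed in neuromuscular genes, with a median log2 difference of -0.701 (Rbpj;MyoD minus DnMaml;MyoD), or -0.427 at the bounds, and the list passed the test. In 17 genes they moved in opposite directions from MyoD-/-; the genes were chosen by their opposite calls, so that their difference also passed the test adds no independent support. Among 718 detected probes without a gene name, which no comparison in the report uses, 147 were called in MyoD-/- against wild type, 71 higher and 76 lower. The DnMaml;MyoD mutant had 55 such probes called and the Rbpj;MyoD mutant 143, each against MyoD-/-, and 30 differed between the double mutants.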

How the results depend on the processing

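The covariate for Eif2s3y, the fits without the 3 arrays with the fewest detected probes, the fits of chip sets 4, 5 and 6+7 only, and leaving out each replicate of the groups with more than 5 were chosen after seeing the data; the other alternatives were planned. Single named genes were compared under the alternatives other than left-out samples and single left-out chip sets. The fit of chip sets 4, 5 and 6+7 only was among these alternatives. Of the values 3436 kept direction and side of the threshold, 258 lost the call, 6 gained it and 9 changed sign. The lists that passed were retested with the correlation estimated, by fry and with every array as its own replicate: 90 of these values kept both, 39 lost the call and 0 changed sign. This does not cover the scalings, under which the medians of Notch components in MyoD-/- and of growth factor genes in the Rbpj;MyoD mutant changed sign. Where no cause is named below, the cause was not tested. Signal over background limits the dim genes: Rbpj, Pax3, Hes5 and Hey2 were detected in 0 arrays.

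A log2 change of at least 1, which leaves fewer genes by construction, gave 150 for MyoD-/- against wild type, 99 for the DnMaml;MyoD mutant, 327 for the Rbpj;MyoD mutant and 146 between the double mutants. In the same order, arrays scaled to a common median gave 1172, 353, 1065 and 192 genes, with 194 shared calls and 1 gene for MyoD+/-. Without a chip term 1170 and 481 genes were called for MyoD-/- and the DnMaml;MyoD mutant, with 279 shared. Sample weights gave 3668 for the Rbpj;MyoD mutant, 1134 between the double mutants and 710 shared. Between the double mutants every array as its own replicate gave 588. That fit holds more replicates and a term for each single chip, and which of these matters was not tested. Only these genotypes in the fit gave 71. In that fit chip sets 1, 2 and 3 hold only 1 of the genotypes each, and fewer samples give the spread. With the correlation estimated 15 of 43 lists kept the call.

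With the replicate number as a block on unmerged arrays and no chip term, 1416 genes were called for the DnMaml;MyoD mutant, 447 for MyoD+/- and 513 between the double mutants, with 1008 shared calls. MyoD-/- against wild type had 2216 and the Rbpj;MyoD mutant 2608 under this block. The numbers do not pair the samples: over 63 pairs of arrays with the same number the median correlation of residuals was -0.018, and over 765 pairs with different numbers -0.009.

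Leaving out chip set 2 gave 885 genes for MyoD-/- against wild type, 444 for the DnMaml;MyoD mutant and 273 shared. Leaving out chip set 5 gave 391 for the DnMaml;MyoD mutant, 1049 for the Rbpj;MyoD mutant and 195 shared. Between the double mutants 223 were called without chip set 4 and 193 without chip set 6+7, and for MyoD+/- 6 without chip set 6+7. Single chip sets hold few samples. For MyoD-/- against wild type, set 1 alone gave 33, set 2 gave 325, set 4 gave 2, and sets 5 and 6+7 gave 0 by limma. For the DnMaml;MyoD mutant, sets 1, 2, 4, 5 and 6+7 gave 7, 22, 3, 0 and 6. For the Rbpj;MyoD mutant, sets 3, 4, 5 and 6+7 gave 245, 3, 449 and 23, and between the double mutants sets 4, 5 and 6+7 gave 1, 0 and 3. On sets 4, 5 and 6+7 taken singly only the pair of MyoD-/- samples gives the spread, and single samples are assumed to vary like them. Chip sets 4, 5 and 6+7 together gave 846 genes for MyoD-/- against wild type, of which 628 are shared with the full fit.

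Leaving out 1 sample at a time gave 1628 to 2071 genes for MyoD-/- against wild type and 509 (without DnMaml;MyoD replicate 6) to 919 for the DnMaml;MyoD mutant. The Rbpj;MyoD mutant had 1146 (without its replicate 5) to 1846, and MyoD+/- 0 to 6 (without its replicate 3-4). Between the double mutants there were 210 (without Rbpj;MyoD replicate 5) to 441, with 225 without Rbpj;MyoD replicate 6-7. Of called named genes, 6 of 70, 13 of 57, 12 of 79 and 9 of 34 lost the call in at least 1 of these fits. Without the 3 arrays with the fewest detected probes the counts were 2007, 876, 1852, 0 and 393, and with the Eif2s3y covariate 1734, 773, 1813, 0 and 330, in the order of the comparisons.

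On chip sets 4, 5 and 6+7 only, the changes in MyoD-/- against wild type turned to -0.133 for Col5a3, -0.357 for Thbs1 and 0.006 for Tgfb2. Myod1 in the DnMaml;MyoD mutant turned to -0.032 with arrays scaled to a common median, -0.018 without a chip term and -0.078 with the replicate block. Notch1 in the Rbpj;MyoD mutant turned to 0.135 with the replicate block. Maml1 between the double mutants turned to -0.041 without a chip term and -0.011 with the replicate block.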

Other observations

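The comparison of chip sets 1 and 2 with chip sets 4, 5 and 6+7 was chosen after the result was seen. The other tests here were planned. Some genes of low oxygen and sugar use were higher in the double mutants than in MyoD-/-, but the list passed in neither with an estimated correlation. In the Rbpj;MyoD mutant 6 of 10 hypoxia and glycolysis genes rose and 0 fell, also adjusted over the list alone, with the vessel growth factor Vegfa at 0.74 ± 0.11 and the peptide hormone Adm at 0.90 ± 0.15. Another of the 6, Pdk1, lost its call without Rbpj;MyoD replicate 1 (adjusted p = 0.0714) or 5 (0.0502). The list median was 0.30 (adjusted p = 3.12e-03; chip-set medians 0.10 to 0.44), and adjusted p = 0.162 with an estimated correlation and 1.43e-04 by fry. With DnMaml 3 of 10 rose and 0 fell (7 and 0 adjusted over the list alone), among them Adm (0.72 ± 0.14) and Aldoa, which lost its call without MyoD-/- replicate 6 or DnMaml;MyoD replicate 2, 3, 4 or 5 (adjusted p = 0.0563 to 0.0803), with a median of 0.29 (adjusted p = 2.51e-03; chip-set medians -0.04 to 0.47) and adjusted p = 0.157 with an estimated correlation and 1.67e-03 by fry. In MyoD-/- against wild type 2 rose, such as Adm (1.29 ± 0.13, detected in 1 of 10 wild-type arrays), and 1 fell, the glycolytic Pfkl (-0.44 ± 0.10, and -0.21 ± 0.21 by a second probe), also adjusted over the list alone (median 0.06, or 0.03 at the bounds, adjusted p = 0.494). Immediate early and stress genes had 2 higher and 0 lower of 12 in the Rbpj;MyoD mutant, also adjusted over the list alone (median 0.37, adjusted p = 0.0102, and adjusted p = 0.313 with an estimated correlation and 0.0113 by fry). With DnMaml 2 were higher and 1 lower (7 and 1 adjusted over the list alone; median 0.38, adjusted p = 8.86e-03, and adjusted p = 0.311 with an estimated correlation and 0.0262 by fry). In MyoD-/- the repressor of cytokine signalling Socs3 fell by -0.90 ± 0.14, as 1 of 2 falls against 1 rise (1 and 3 adjusted over the list alone; median -0.09, or 0.033 with arrays scaled to a common median, adjusted p = 0.582).

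Gap43, a growth-cone protein on the neuronal list, rose in all 3 comparisons, by 1.18 ± 0.10 in MyoD-/- against wild type, and against MyoD-/- by 0.95 ± 0.11 with DnMaml and 1.16 ± 0.12 without Rbpj. Of the 12 genes fixed for that list 8, such as Tubb3 and Snap25, were on the array but failed the detection filter. Of 4 measured neuronal markers 1 rose in MyoD-/- (median 0.20, adjusted p = 0.0968), 1 with DnMaml (2 adjusted over the list alone; median 0.45, adjusted p = 0.0726) and 3 without Rbpj (median 0.95, adjusted p = 0.0102, and adjusted p = 0.0492 with an estimated correlation and 2.08e-07 by fry; chip-set medians 0.69 to 1.08); 0 fell. Of these 3, Stmn2 (detected in 3 of 7 and 1 of 18 arrays) and Nefm lost the call without Rbpj;MyoD replicate 6-7 (adjusted p = 0.0525 and 0.128), Stmn2 also without replicate 4 (0.0529), and Nefm also without replicate 2 (0.11) or 5 (0.0605) or MyoD-/- replicate 7 (0.0751). Adipocyte markers had 1 of 5 higher with DnMaml, Lpl, a call lost without DnMaml;MyoD replicate 6 (adjusted p = 0.0524) (4 adjusted over the list alone; median 0.93, adjusted p = 0.0182), with adjusted p = 0.311 with an estimated correlation and 0.0317 by fry. Without Rbpj 2 of 5 rose, Lpl, lipoprotein lipase (1.12 ± 0.16), and Ebf2. There the median was -0.29, or 0.00 at the bounds, while the test pointed up (adjusted p = 0.253). That 0.00 is the value set for a gene without a bound. In MyoD-/- against wild type Lpl fell by -0.71 ± 0.14 and Pparg rose (adjusted p = 0.946 for the list). Smooth muscle and pericyte markers had 0 higher and 2 lower of 6 in MyoD-/-, Acta2 (-0.65 ± 0.11) and Tagln (-0.78 ± 0.14), with adjusted p = 0.085. Against MyoD-/- they divided into 2 higher and 1 lower with DnMaml (adjusted p = 0.654) and 2 higher and 2 lower without Rbpj (adjusted p = 0.946), with Tagln at -1.02 ± 0.15 and -1.15 ± 0.16, near background in both, since 1 of 8 and 1 of 7 arrays detected it.

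The tendon and cartilage list did not pass as a list (adjusted p = 0.654 in MyoD-/-, 0.0532 with DnMaml and 0.797 without Rbpj), but single members did. Of 6, 0 were called in MyoD-/-, 1 rose with DnMaml, the homeobox gene Mkx (0.80 ± 0.23, detected in 8 of 18 MyoD-/- arrays), and without Rbpj Mkx rose (1.02 ± 0.25) and Scx fell (-0.72 ± 0.20). Mkx lost its call with DnMaml without MyoD-/- replicate 2 or 4 or DnMaml;MyoD replicate 1, 2 or 6 (adjusted p = 0.0504 to 0.0885), and Scx without Rbpj;MyoD replicate 3 (0.0509). The endothelial list did not pass either (adjusted p = 0.242, 0.144 and 0.946 in the same order). Of its 5 members Egfl7 alone was called, lower in MyoD-/- (-0.63 ± 0.09) and higher with DnMaml (0.48 ± 0.09), and 0 were called without Rbpj by limma. Pecam1, which encodes the gated CD31, was detected in 2 of 18 MyoD-/- and 3 of 10 wild-type arrays. The Schwann cell list gave adjusted p = 0.582 in MyoD-/-, where 1 of 3 fell, Ngfr (adjusted p = 0.0317, and 0.0506 to 0.11 without wild-type replicate 3, 4, 7 or 8 or MyoD-/- replicate 11, 13 or 15-17), and 0.166 without Rbpj, where Ngfr rose (adjusted p = 6.36e-07). Krt10, the 1 measured keratinocyte marker, changed by -0.23 ± 0.10 in MyoD-/- (adjusted p = 0.0819), 0.16 ± 0.10 with DnMaml (0.383) and -0.17 ± 0.11 without Rbpj (0.297).

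Chip sets 1 and 2 are here called early and chip sets 4, 5 and 6+7 late. These names follow the chip numbers, not dates. Between early and late chips the change from wild type to MyoD-/- differed in 10 genes, of which 7 were called over all chips. An unadjusted p under 0.05 was found for 893 genes, where 433 are expected. The largest were Sel1l3 (late minus early -2.35 ± 0.30) and Etv2 (-2.02 ± 0.30), and the acetylcholine receptor gene Chrna1 was among them (-1.08 ± 0.21, adjusted p = 0.0271). For DnMaml 2 genes differed, Cxcl5 (-1.96 ± 0.28) and Gpr17 (-1.23 ± 0.22), while 901 had an unadjusted p under 0.05, where 433 are expected.

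In MyoD+/- against wild type 6 more lists passed the test although limma called 0 genes and 314 had an unadjusted p under 0.05. They were adipocyte (median 0.47, adjusted p = 3.83e-03), cell cycle (-0.16, 8.82e-03), fibroblast (0.44, 0.0142), leukocyte (0.63, 0.0151), erythroid (0.73, 0.0163) and immediate early genes (0.23, 0.0283). With an estimated correlation their adjusted p ran from 0.0631 for leukocyte to 0.385 for immediate early genes, and by fry the leukocyte list had 0.0448 and immediate early genes 0.36.

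Among 100 splits of the samples, the real one included, 1 gave as many genes as the real split in MyoD-/- against wild type (1914 genes, highest other 34), in the DnMaml;MyoD mutant (763, highest other 152), in the Rbpj;MyoD mutant (1742, highest other 273) and between the double mutants (341, highest other 62). No other split reached these 4 counts. The splits were drawn without regard to chip set and mix the genotypes, which widens the spread within groups, so they do not exclude chance outright. For MyoD+/- against wild type the real count is 0, which each of the 100 splits reaches by construction, so the splits decide nothing there. The highest other split called 226 genes, which points to a structure of the samples whose source was not tested.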
